A study of Homo sapiens with 16 samples.

How the data were processed

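RNA from the human multiple myeloma cell line MM1.S was measured on 16 Illumina bead arrays. Per the labels, the cells received 1 uM dexamethasone for 0 or 4 h, and total RNA and 3 pools (A, B and C) of RNA from fractionated polysomes were collected, with 2 arrays in each of 8 groups. The sucrose was removed from the pools with isopropanol and a phenol and chloroform step, and a biotin label was added with an Ambion amplification kit, per the labels' protocols. Which part of the gradient each pool covers, how cells were lysed and how scans were read out are not given in the sources used here.

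The deposited non-normalized table holds, for 47323 probes and each array, a linear intensity and a detection p-value, per the file headers. The columns of that table carry a prefix N or X in front of the time and the pool letter. The meaning of the prefix is not given in the sources used here, and it names an array within its group and, in alternatives and tests added after the data were seen, the arrays of equal prefix. The deposited value table holds normalized log2 values of the same 16 samples. Its scale was taken from its own values; how the authors normalized and whether they centred it stay unknown. Its column medians for replicates 1 and 2 were 7.21 and 7.211 in untreated total RNA, 7.21 and 7.21 in treated total RNA, 7.336 and 7.348 in untreated pool A, and 7.311 and 7.409 in treated pool A. They were 7.285 and 7.305 in untreated pool B, 7.259 and 7.342 in treated pool B, 7.237 and 7.298 in untreated pool C, and 7.267 and 7.297 in treated pool C. Each non-normalized array correlated best with a value column of its own group (16 of 16, smallest r = 0.99669 across probes), with the 8 N arrays nearest to replicate 1 and the 8 X arrays nearest to replicate 2. The direction of all values was that of intensity. A probe's detection p-value was taken to compare it with negative control beads, which the column headers do not state. The files name no slide.

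Intensities were background-corrected with the normexp method of limma (nec, on detection p-values, offset 16), quantile-normalized over the 16 arrays and put on a log2 scale in R 4.3.3 with limma 3.58.1. A change is therefore relative to the other genes on the array, and folds of dim genes are understated. Probes were kept where the detection p-value was under 0.01 on at least 2 arrays, which left 17269 probes. The annotation table lists 30121 of the probes, 30113 with 1 gene symbol and 8 with several, and 17202 are unnamed here. Of the annotated probes, 30074 matched the reference gene table, from which current symbols were taken. Of the kept probes, 13289 had 1 symbol and 3980 had no single symbol and were tested apart. The probe with the highest mean stood for each of the 10163 genes, of which 2550 had more than 1 kept probe. A gene whose chosen probe was detected on no array of a group was taken as not above background there, and its other kept probes were not consulted. Its fold is given as "at least" the ratio of the brighter group to the higher, on each array, of the lowest detected signal and the gene's own signal, and no fold is given where that ratio is under 1.

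A mean was fitted for each of the 8 groups with limma (lmFit, contrasts, eBayes), so that all groups shared 1 estimate of the spread with 8 residual and 5.36 prior degrees of freedom. The 14 comparisons were 4 h against 0 h in each of the 4 kinds of RNA, 4 differences between those responses, and 6 contrasts among pools and total RNA at 0 h. P-values were adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05. Errors of genes are standard errors from limma. Gene lists for a glucocorticoid-treated plasma cell line and for polysome fractions were written before the data were examined, as were the design, the alternatives and the rule for named genes. The 25 lists with at least 3 tested members were tested against all other genes with camera (inter-gene correlation preset at 0.01), and with camera with an estimated correlation as an alternative. The other alternative, fry, tests a list against no change and not against other genes. A list's shift is the mean of its members minus the mean of all genes, with a standard error over genes, which are not independent replicates. A further list of 15 mitochondrially encoded genes had 0 members under the symbols used and was not analysed here.

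By the rule for named genes, those past the threshold whose arrays did not overlap between groups were ranked by absolute log2 change. The top 12 each way were eligible for dexamethasone in total RNA and for pool C against pool A, and the top 6 each way elsewhere. Where no gene passed, the 3 with the smallest p-values each way were eligible as values. Up to 4 members per list and comparison were added, together with NR3C1, TSC22D3, FKBP5, BCL2L11, DDIT4, TXNIP, MYC, IRF4, MCL1, XBP1, ATF4, EIF4E and EIF4EBP1. The text names a part of these.

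The method was tested on simulated arrays with 200 of 10163 genes changed. A log2 change of 1 was recovered for 42% of changed genes in total RNA and 38% in pool A, and a change of 2 for 90% and 92.5%. For the difference between the responses of pool A and total RNA, a log2 difference of 1 was recovered for 0% of genes and a difference of 2 for 73.5%. A list of 30 genes shifted by 0.5 was found in 100 of 100 runs, and an unchanged list had a p-value below the threshold in 4 of 100. The simulated errors were independent between genes, with 1 spread per gene for all groups. In the data the SD of the difference between the 2 arrays ranged from 0.3014 (treated total RNA) to 0.5807 (untreated pool A). Genes of a list that vary together were not simulated, so these rates hold for the simulated setting only.

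Alternatives were no background correction, median scaling, quantile normalization within each kind of RNA, the deposited value table, no filter, detection on all 16 arrays, the mean of a gene's probes, only the groups compared, eBayes with trend and robust settings, and leaving out each array. Replicate and culture blocks had been planned for the same arrays but were not run on them, since replicate numbers stand on the value table only. After the data were seen, a block for the column prefix, array weights per kind of RNA, the value table with a replicate or a culture block, and a fit without the 4 untreated X arrays were added. The number of arrays limits the precision. The labels number the arrays of a group but do not say that they come from separate cultures, so p-values measure only the spread between these samples, which may be technical.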

Results

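MM1.S is a multiple myeloma line, a malignant counterpart of the antibody-secreting plasma cell, and dexamethasone is a synthetic glucocorticoid that activates the glucocorticoid receptor NR3C1. Total RNA and 3 pools of RNA from polysomes fractionated in sucrose were profiled after 0 or 4 h with 1 uM dexamethasone on 16 arrays, 2 in each of 8 groups. Polysomes are mRNAs with several ribosomes, and the part of the gradient that each pool covers is not given in the sources used here. Between 26.11% and 31.3% of the 47323 probes were detected on an array, and median intensities lay between 129.4 and 176.6. Correlations between the 2 arrays of a group, across genes, ranged from 0.9659 in untreated pool A to 0.9906 in treated total RNA. The standard deviation of the difference between the 2 arrays was 0.5807 log2 units in the first of these groups and 0.3014 in the second. The 2 arrays of a group are called N and X after the prefix of their columns. Every n below is 2 arrays per group, except in fits that leave out arrays, where an affected group has 1 array.

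In total RNA, 11 of 10163 genes differed between 4 h and 0 h, 9 higher and 2 lower (limma). CEP70, a centrosomal protein, rose by 2.30 ± 0.34 log2 units (4.92-fold, adjusted p = 0.0207). HMGB3, an HMG-box protein, rose by 1.55 ± 0.20 (2.93-fold, adjusted p = 0.0131), the linker histone H1-10 by 1.23 ± 0.19 (2.35-fold, adjusted p = 0.0207) and HMCES, which binds abasic sites in single-stranded DNA, by 1.51 ± 0.20 (2.85-fold, adjusted p = 0.0131). SERTAD2, a transcriptional coregulator, rose 2.83-fold (adjusted p = 0.0181) and RGCC, a cell cycle regulator, by 1.25 ± 0.18 log2 units (adjusted p = 0.0181). The Wnt receptor FZD4 and the corepressor TLE1 were not above background at 0 h on either array and rose at least 2.40-fold (adjusted p = 0.0341) and at least 1.77-fold (adjusted p = 0.0427). CEMIP, a hyaluronan-binding protein, also passed (adjusted p = 0.0341), from a level below background at 0 h. The chemokine receptor CCR1 fell by 1.61 ± 0.21 log2 units (3.04-fold lower, adjusted p = 0.0131) and DUSP5, a phosphatase of ERK kinases, fell by 1.11 ± 0.18 (adjusted p = 0.0341). At an unadjusted p under 0.05 there were 463 genes, against 508 expected by chance. Leaving out any 1 of the 4 total RNA arrays left 0 calls, with 253 (untreated N), 419 (untreated X), 343 (treated N) or 281 genes (treated X) at an unadjusted p under 0.05. Median scaling gave 3 higher and 2 lower.

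The list of glucocorticoid receptor targets was shifted by 0.72 ± 0.14 log2 units relative to all genes in total RNA (camera adjusted p = 4.09e-12), and 28 of its 34 members had positive differences. The adjusted p was 0.0668 with an estimated correlation. No member passed over all genes (0 in limma, 14 at an unadjusted p under 0.05), and 7 were higher adjusted over the list alone. TSC22D3, the glucocorticoid-induced leucine zipper, differed by 2.17 ± 0.82 (adjusted p = 0.868), the receptor co-chaperone FKBP5 by 2.13 ± 0.54 (adjusted p = 0.281) and the chemokine receptor CXCR4 by 2.23 ± 0.64 (adjusted p = 0.44). The 2 untreated arrays differed in these genes. TSC22D3 stood at 10.0 on the N array and 12.4 on the X array at 0 h, and at 13.3 and 13.4 at 4 h. DDIT4, an inhibitor of the kinase complex mTORC1, stood at 9.84 and 13 at 0 h and at 13.7 and 13.9 at 4 h, and FKBP5 at 9.48 and 11.1 and then at 12.3 and 12.5. Without the 4 untreated X arrays, an alternative added after seeing the data, 26 genes passed in total RNA, 21 higher and 5 lower, 4 of them among the 11. TSC22D3 was then at 3.36, DDIT4 at 3.99 and FKBP5 at 2.92. The X arrays were left out after these 3 genes had been seen to stand high on them. Their larger differences follow from that choice and are no test of them. Each untreated group then held 1 array, so the spread came from the treated groups. With these fewer arrays CEP70 was at 2.34 (adjusted p = 0.152), RGCC at 1.25 and H1-10 at 1.26 (adjusted p = 0.115 each) and DUSP5 at -1.09 (adjusted p = 0.144). These did not pass, and neither did FZD4 (adjusted p = 0.213), TLE1 (adjusted p = 0.141) or CEMIP (adjusted p = 0.149).

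**Figure D1:**
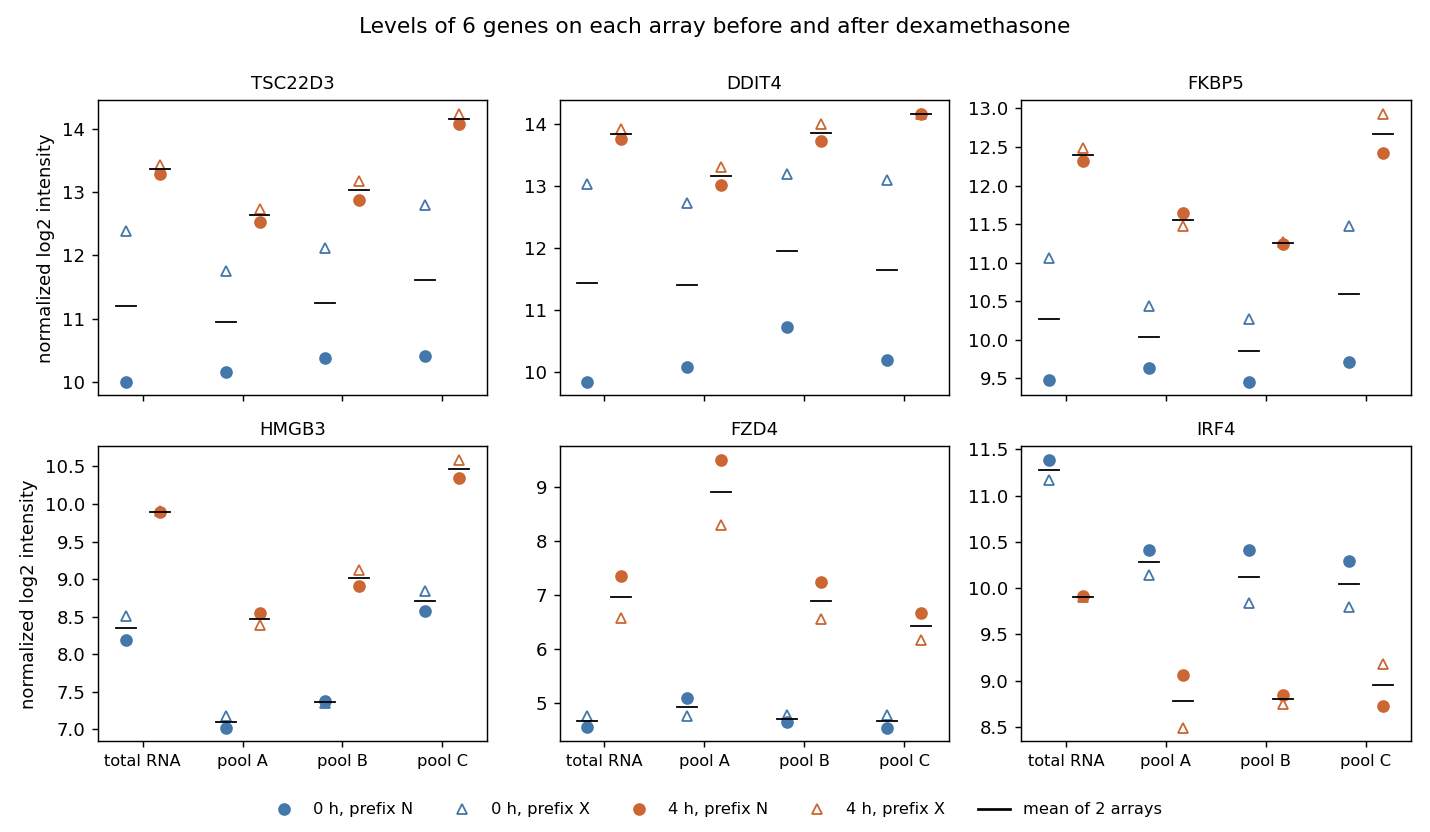
Normalized log2 intensity of 6 genes on each array (vertical axis) in total RNA and pools A, B and C at 0 and 4 h; filled circles are N arrays, open triangles X arrays and lines the mean of 2 arrays. TSC22D3 in untreated total RNA lies at 10.0 on the N and 12.4 on the X array.

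Other fixed lists moved less in total RNA. Heat shock genes, which encode chaperones, were shifted by -0.29 ± 0.06 relative to all genes (17 of 20 members negative, adjusted p = 0.000291), and adjusted p was 0.404 with an estimated correlation. MYC targets and nucleolar ribosome-assembly genes were shifted by -0.23 ± 0.05 (22 of 27 negative, adjusted p = 0.000291), with an adjusted p of 0.404 with an estimated correlation. Sterol synthesis genes were shifted by -0.23 ± 0.05 (17 of 20 negative, adjusted p = 0.00439, and adjusted p = 0.533 with an estimated correlation). In these 3 lists, 0 members passed over all genes in limma, with 2, 2 and 1 at an unadjusted p under 0.05, and 1 nucleolar gene was lower adjusted over the list alone. HSPA1B, an inducible HSP70, differed by -1.0 ± 0.36 (adjusted p = 0.799), RRS1, which acts in assembly of the large ribosomal subunit, by -0.85 ± 0.21 (adjusted p = 0.239) and DHCR7, the enzyme of the last step of cholesterol synthesis, by -0.63 ± 0.26 (adjusted p = 0.996). The sterol list was at an adjusted p of 0.336 without the 4 untreated X arrays, 0.31 without the untreated X array of total RNA alone and 0.431 without its treated N array, with a shift of -0.35 (adjusted p = 3.65e-05) without its treated X array, and heat shock genes were at 0.0758 without the untreated N array and 0.0746 without the treated X array. BCL2 family genes, which control apoptosis, were not shifted past the threshold (15 members, adjusted p = 0.652). Its members BMF (0.93 ± 0.38, adjusted p = 0.975) and BCL2L11 (0.18 ± 0.26), both pro-death, and the pro-survival BCL2L1 (-0.90 ± 0.34, adjusted p = 0.876) and MCL1 (-0.38 ± 0.22) did not pass singly. IRF4, a transcription factor on which myeloma cells depend, differed by -1.37 ± 0.27 (adjusted p = 0.0757), MYC by -0.24 ± 0.20 and the receptor gene NR3C1 by 0.31 ± 0.43.

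**Figure D2:**
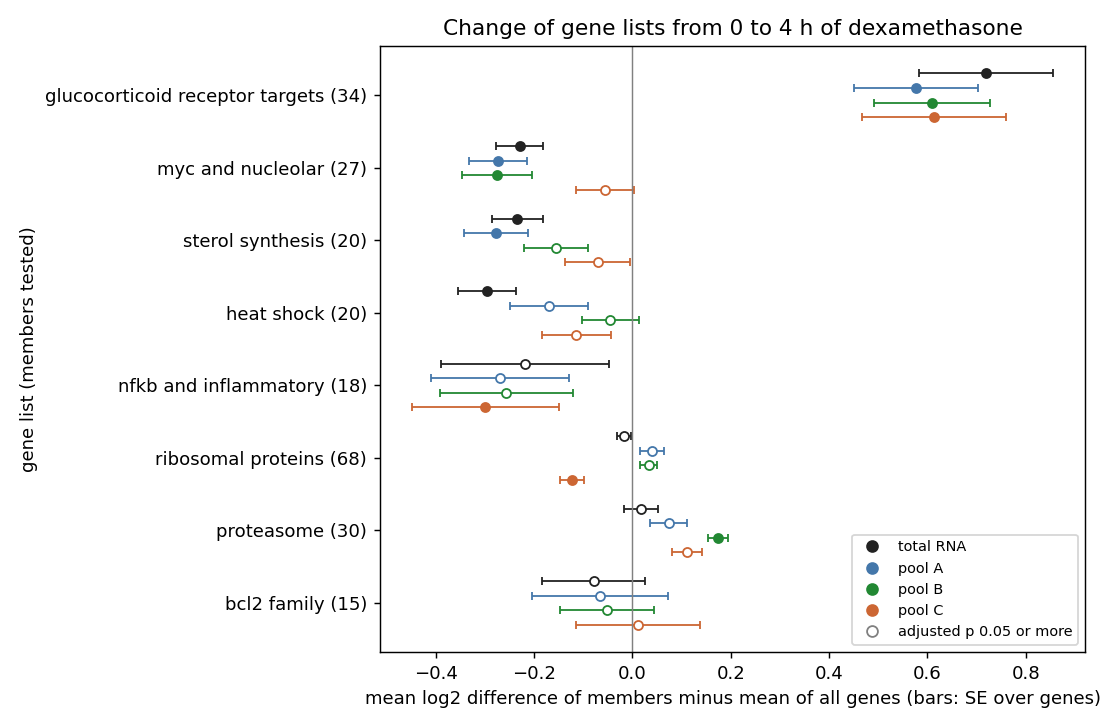
Mean log2 difference of 8 gene lists between 4 and 0 h minus the mean of all genes (horizontal axis), per kind of RNA; bars are standard errors over genes and open symbols have an adjusted p of 0.05 or more. Glucocorticoid receptor targets lie at 0.72 in total RNA, 0.58 in pool A, 0.61 in pool B and 0.61 in pool C.

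The next comparisons asked the same of the 3 pools. In pool A, 64 genes were higher and 25 lower at 4 h, and 1318 had an unadjusted p under 0.05. FZD4 rose at least 7.45-fold (adjusted p = 0.000394) and the ubiquitin ligase TRIM31 at least 4.36-fold (adjusted p = 0.000394), both from levels below background at 0 h. TGFBR2, a receptor for TGF-beta, rose at least 4.41-fold (adjusted p = 0.00346). CEP70 rose by 2.69 ± 0.34 (6.46-fold, adjusted p = 0.00371). FAR2, a fatty acyl-CoA reductase, and FAIM, an inhibitor of Fas-driven apoptosis, were each detected on 1 of 2 untreated arrays and rose by 2.43 ± 0.46 (adjusted p = 0.029) and 2.16 ± 0.39 (adjusted p = 0.027). IRF4 fell by 1.51 ± 0.27 (2.84-fold lower, adjusted p = 0.0253). The metallothionein MT1E fell at least 1.67-fold (adjusted p = 0.0205) and the small nucleolar RNA SNORD87 at least 2.28-fold (adjusted p = 0.00371). TNFRSF21, a death receptor detected on 1 of 2 treated arrays, fell by 1.54 ± 0.29 (adjusted p = 0.0278), and the pseudogene HERC2P2 by 1.58 ± 0.21 (2.98-fold lower, adjusted p = 0.00451). In the fit of the pool A arrays alone 0 genes passed (789 at an unadjusted p under 0.05), and the count was 13 without the treated N array and 38 without the treated X array. Without the untreated N array 46 genes were higher and 45 lower, 33 of them among the 89. Median scaling moved the median of all genes by 0.22 in place of 0.04 and gave 41 higher and 2 lower.

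Glucocorticoid receptor targets were shifted by 0.58 ± 0.13 in pool A relative to all genes (30 of 34 positive, camera adjusted p = 6.92e-05, and adjusted p = 0.656 with an estimated correlation), with 1 member higher over all genes and 2 adjusted over the list alone. TSC22D3 differed by 1.68 ± 0.82 (adjusted p = 0.413), FKBP5 by 1.52 ± 0.54 (adjusted p = 0.255) and KLF9, a transcription factor induced by glucocorticoids, by 2.17 ± 0.69 (adjusted p = 0.189). In untreated pool A, TSC22D3 was at 10.1 on the N and 11.7 on the X array. Without the untreated X arrays, TSC22D3 was at 2.48, FKBP5 at 1.92 and KLF9 at 2.84 in pool A. These larger differences follow from leaving out arrays on which the 3 genes stood high, and 1 untreated array remained. CEP70 was then at 2.42 (adjusted p = 0.0538). Sterol synthesis genes were shifted by -0.28 ± 0.07 (16 of 20 negative, adjusted p = 0.0153, and adjusted p = 0.667 with an estimated correlation). MYC targets and nucleolar genes were at -0.27 ± 0.06 (20 of 27 negative, adjusted p = 0.0153), with an adjusted p of 0.667 with an estimated correlation. Both lists had 0 members called over all genes and 0 adjusted over the list alone (limma, 3 each at an unadjusted p under 0.05). Leaving out the untreated N array of pool A brought glucocorticoid receptor targets to an adjusted p of 0.0699. Leaving out any 1 pool A array brought the sterol and the nucleolar lists to adjusted p-values between 0.0516 and 0.0831, and the sterol list was at 0.0923 without all 4 untreated X arrays. In the deposited value table the nucleolar list was at -0.08 (adjusted p = 0.131).

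In pool B, 3 genes were higher and 0 lower, with 681 at an unadjusted p under 0.05 in limma. HMGB3 rose by 1.65 ± 0.20 (3.15-fold, adjusted p = 0.0101), HMCES by 1.37 ± 0.20 (2.58-fold, adjusted p = 0.0378) and H1-10 by 1.28 ± 0.19 (2.43-fold, adjusted p = 0.0378). Glucocorticoid receptor targets were shifted by 0.61 ± 0.12 relative to all genes (28 of 34 positive, camera adjusted p = 2.15e-08, and adjusted p = 0.185 with an estimated correlation). None passed over all genes (0 in limma, 11 at an unadjusted p under 0.05) and 4 were higher adjusted over the list alone. TSC22D3 was at 10.4 on the N and 12.1 on the X array at 0 h and differed by 1.78 ± 0.82 (adjusted p = 0.74). Proteasome genes were shifted by 0.17 ± 0.02 (28 of 30 positive, adjusted p = 0.0075, and adjusted p = 0.669 with an estimated correlation), and PSMC6, a subunit of its cap, differed by 0.46 ± 0.26 (adjusted p = 0.86). Translation factors were shifted by 0.19 ± 0.04 (17 of 19 positive, adjusted p = 0.0311, and adjusted p = 0.862 with an estimated correlation). MYC targets and nucleolar genes were shifted by -0.28 ± 0.07 (19 of 27 negative, adjusted p = 0.0075, and adjusted p = 0.675 with an estimated correlation). RRP12, a ribosome-assembly factor of that list, differed by -1.18 ± 0.36 (adjusted p = 0.434). These 3 lists had 0 members called over all genes and 0 adjusted over the list alone (limma), with 4 nucleolar genes and 0 of the others at an unadjusted p under 0.05. Without the untreated X arrays, TSC22D3 was at 2.65. That larger difference follows from leaving out arrays on which this gene stood high, and 1 untreated array remained. With these fewer arrays HMCES at 1.45 (adjusted p = 0.0793), H1-10 at 1.14 (adjusted p = 0.116) and the proteasome list at 0.16 (adjusted p = 0.2) did not pass. The translation factor list was then at 0.29 and the nucleolar list at -0.42. In untreated pool B the mean X minus N differences of these lists were 0.17 and -0.321. Their larger shifts, also without the pool B array X alone, thus follow from leaving out that array and are no test of the lists. The fit of the pool B arrays alone had 0 calls (508 at an unadjusted p under 0.05). Leaving out any 1 pool B array gave 0 calls, with 462 (untreated N), 1314 (untreated X), 589 (treated N) and 523 genes (treated X) at an unadjusted p under 0.05. Median scaling gave 0 higher and 0 lower (656 at an unadjusted p under 0.05, median of all genes -0.12 in place of -0.01), with translation factors at an adjusted p of 0.0733. Glucocorticoid receptor targets were at 0.35 (adjusted p = 0.00463) without the untreated N array, and without the untreated X array nucleolar genes were at -0.42 (adjusted p = 0.00565) and translation factors at 0.29 (adjusted p = 0.0497). Adjusted p was 0.417 for translation factors and for nucleolar genes without the untreated N array, 0.106 for nucleolar genes without the treated N array, 0.18 for proteasome genes without the untreated X array, and 0.544 for translation factors and 0.125 for proteasome genes without the treated X array.

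In pool C, 7 genes were higher and 0 lower, with 603 at an unadjusted p under 0.05 in limma. AP3S1, a subunit of a vesicle adaptor complex, rose by 2.04 ± 0.31 (4.11-fold, adjusted p = 0.0346). HMGB3 rose by 1.76 ± 0.20 (3.38-fold, adjusted p = 0.00248), H1-10 by 1.73 ± 0.19 (3.31-fold, adjusted p = 0.00248) and HMCES by 1.71 ± 0.20 (3.27-fold, adjusted p = 0.00329). The lysosomal membrane protein LAPTM5 rose by 1.44 ± 0.24 (2.71-fold, adjusted p = 0.0485) and TXNIP, an inhibitor of thioredoxin, by 1.40 ± 0.19 (adjusted p = 0.0133). Glucocorticoid receptor targets were shifted by 0.61 ± 0.15 relative to all genes (26 of 34 positive, camera adjusted p = 2.74e-07, and adjusted p = 0.264 with an estimated correlation), 1 higher over all genes and 6 adjusted over the list alone. TSC22D3 was at 10.4 on the N and 12.8 on the X array at 0 h and differed by 2.55 ± 0.82 (adjusted p = 0.512). NF-kB and inflammatory genes were shifted by -0.30 ± 0.15 (13 of 18 negative, adjusted p = 0.0206, and adjusted p = 0.479 with an estimated correlation), 0 lower over all genes and 3 adjusted over the list alone (limma, 3 at an unadjusted p under 0.05). CCL3, an inflammatory chemokine of that list, differed by -2.44 ± 0.62 (adjusted p = 0.3). Ribosomal protein genes were shifted by -0.12 ± 0.02 (51 of 68 negative, adjusted p = 0.0206, and adjusted p = 0.479 with an estimated correlation), with 0 members lower over all genes and 0 adjusted over the list alone (limma, 2 at an unadjusted p under 0.05). RPL26 differed by -0.84 ± 0.20 (adjusted p = 0.23). Without the untreated X arrays, which left 1 untreated array, TSC22D3 was at 3.74, CCL3 at -3.41 and LAPTM5, not past the threshold, at 1.49. The larger difference of TSC22D3 follows from leaving out arrays on which it stood high, and that of CCL3 from leaving out an array on which it stood low. Ribosomal protein genes were then at -0.24 and NF-kB genes at -0.45, with the same shifts without the untreated pool C array X alone. In untreated pool C the mean X minus N differences of these 2 lists were -0.225 and -0.304. Their larger shifts thus follow from leaving out the X array and are no test of the lists. In the fit of the pool C arrays alone 0 genes passed (507 at an unadjusted p under 0.05). The count was 1 without the untreated N array, 3 without the untreated X array, 48 (8 higher, 40 lower) without the treated N array and 0 (422 at an unadjusted p under 0.05) without the treated X array. Median scaling gave 11 higher and 3 lower, and ribosomal protein genes an adjusted p of 0.266. NF-kB genes were at an adjusted p of 0.257 without the untreated N array, 0.169 without the treated X array and 0.104 with no filter on dim probes, and ribosomal protein genes at 0.866 and 0.169 without the same arrays. Glucocorticoid receptor targets were at 0.38 (adjusted p = 0.001) without the untreated N array.

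HMGB3, HMCES and H1-10 passed in all 4 kinds of RNA, and in pool A they rose by 1.37 (adjusted p = 0.00717), 1.45 (adjusted p = 0.00594) and 1.16 log2 units (adjusted p = 0.0149). Of the 9 genes higher in total RNA, 7 also passed the threshold as higher in pool A, 3 in pool B and 3 in pool C. Positive differences, called or not, were found for 8, 8 and 9 of them in these pools. CCR1, lower in total RNA, was also lower in pool A (-1.19, adjusted p = 0.0253).

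Whether a polysome pool responded differently from total RNA was tested directly, and 0 genes passed in any of the 4 differences (limma). At an unadjusted p under 0.05 there were 410 genes for pool A minus total RNA, 172 for pool B, 184 for pool C and 585 for pool C minus pool A. The smallest adjusted p was 0.534 in the first of these and 0.105 in the last. By chance 508 genes were expected in each, so the counts of 410, 172 and 184 lay below chance. On simulated arrays a log2 difference of 1 between the responses of pool A and total RNA was recovered for 0% of genes. The 0 calls therefore do not show that the responses were equal. CEMIP, TRIM31 and MT1E were among the genes with the smallest p for pool A minus total RNA (adjusted p = 0.534 each) and TRIM31 for pool C minus pool A (adjusted p = 0.105), but lay below background in at least 1 group, so no size is given. ZNF76, a zinc finger protein detected on 1 of 2 treated pool A arrays, was at 1.85 ± 0.38 (adjusted p = 0.412) for pool C minus pool A. The heat shock list was 0.25 higher in pool B than in total RNA in its response (15 of 20 positive, camera adjusted p = 0.0176, and adjusted p = 0.94 with an estimated correlation). The proteasome list was 0.16 higher (23 of 30 positive, adjusted p = 0.0385, and adjusted p = 0.94 with an estimated correlation). Both lists had 0 members called over all genes, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 (limma). With the untreated X arrays left out their adjusted p-values were 0.1 and 0.408, with no filter on dim probes 0.328 and 0.125, and the 4 counts of genes were 0 (522, 340, 161 and 791 at an unadjusted p under 0.05). Adjusted p for heat shock genes was 0.398 without the untreated pool B array X, 0.476 without the untreated total RNA array N, 0.175 without the treated pool B array X and 0.406 without the treated total RNA array X. Proteasome genes were at 0.294, 0.0949, 0.556 and 0.286 without these arrays, and at 0.138 without the untreated total RNA array X, where heat shock genes were at 0.37 (adjusted p = 0.000219). Leaving out the untreated N array of pool A gave 16 genes for pool A minus total RNA and 8 for pool C minus pool A.

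The pools were next compared without treatment. Against pool A, pool C had 3472 genes higher and 2173 lower, with changes relative to all genes. The list of noncoding RNAs was lower in pool C. The small nucleolar RNA SNORD96A fell by 6.71 ± 0.21 (105-fold lower, adjusted p = 6.27e-10, detected on 1 of 2 pool C arrays), SNORD83B was at least 53.1-fold lower (adjusted p = 3.09e-09), SNORA61 44.2-fold and RN7SK, which holds back the elongation factor P-TEFb, 48.1-fold lower (adjusted p = 4.4e-08). ZFAS1, a host transcript of small nucleolar RNAs, was 18.8-fold lower (adjusted p = 7.25e-09). Of 23 noncoding RNAs, 18 were lower and 0 higher, and 22 were lower adjusted over the list alone (shift -3.00 ± 0.32, camera adjusted p = 1.62e-13), with an adjusted p of 0.00202 with an estimated correlation. Among mRNAs, CBX1, a heterochromatin protein, was at least 7.37-fold higher in pool C (adjusted p = 2.22e-08), the signal peptidase subunit SPCS3 10.6-fold (adjusted p = 5.9e-07), the shelterin protein TINF2 11.5-fold (adjusted p = 8.7e-08) and HMGN5, a nucleosome-binding protein, 15.3-fold (adjusted p = 1.86e-05).

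Proteasome genes were higher in pool C than in pool A for 28 of 30, and for 29 adjusted over the list alone (1.5 ± 0.13, camera adjusted p = 7.11e-09, and adjusted p = 0.0435 with an estimated correlation). PSMB2 was 8.99-fold and PSMB3 8.09-fold higher. Unfolded protein response genes were higher for 18 and lower for 2 of 25, with 19 and 2 adjusted over the list alone (0.85 ± 0.19, adjusted p = 0.00395, and adjusted p = 0.405 with an estimated correlation). The endoplasmic reticulum co-chaperone DNAJB11 was 5.33-fold and MANF, a secreted factor of the same compartment, 4.77-fold higher. Genes of plasma cell identity were higher for 16 and lower for 2 of 27, with 17 and 3 adjusted over the list alone (0.68 ± 0.16, adjusted p = 0.0207, and adjusted p = 0.302 with an estimated correlation). They included TNFRSF17, the receptor BCMA, at 4.21-fold and MZB1, an antibody-assembly chaperone, at 4.00-fold higher. Ribosomal protein genes were lower for 22 and higher for 2 of 68, with 21 and 2 adjusted over the list alone (-0.49 ± 0.09, adjusted p = 0.00395, and adjusted p = 0.405 with an estimated correlation). RPL23A was 5.71-fold lower and RPS7 4.94-fold higher. The stress transcription factor ATF4 was 4.35-fold lower (adjusted p = 4.13e-05), its target DDIT3 at least 10.98-fold lower (adjusted p = 1.08e-07) and MYC 2.01-fold higher (adjusted p = 0.000858). Median scaling placed the median gene at 1.16 in place of 0.26 and gave 6543 higher and 920 lower, with the ribosomal list at -1.37 (adjusted p = 2.26e-16) and the plasma cell list at an adjusted p of 0.0546. The fit without the untreated X arrays gave 2396 genes higher and 1698 lower, with the ribosomal list at an adjusted p of 0.0842.

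Pool B had 1446 genes higher and 1087 lower than pool A. The nuclear transport factor NUTF2 was 8.67-fold higher (adjusted p = 4.91e-05). Among noncoding RNAs, SNORD96A was 53.7-fold (adjusted p = 4.82e-09), SNORD83B 50.2-fold and RN7SK 15.5-fold lower. Of the 23, 13 were lower and 1 higher, with 16 and 1 adjusted over the list alone (-1.53 ± 0.30, camera adjusted p = 1.59e-09, and adjusted p = 0.00685 with an estimated correlation). Nuclear-encoded genes of oxidative phosphorylation were higher for 28 and lower for 1 of 58, with 33 and 1 adjusted over the list alone (0.55 ± 0.07, adjusted p = 5.36e-07, and adjusted p = 0.599 with an estimated correlation). The complex I subunits NDUFB7 and NDUFS5 were 2.91-fold and 2.71-fold higher. Translation factors were lower for 5 of 19 over all genes and for 5 adjusted over the list alone (-0.53 ± 0.12, adjusted p = 0.00309, and adjusted p = 0.599 with an estimated correlation), among them PABPC1, the poly(A)-binding protein, at 4.25-fold lower (adjusted p = 0.000118). BCL2L11 was 2.82-fold higher (adjusted p = 0.00108) and EIF4EBP1, a repressor of cap-dependent translation, 2.23-fold higher (adjusted p = 0.0177). Median scaling gave 3321 higher and 485 lower around a median gene of 0.45 in place of 0.08. With the untreated X arrays left out, 435 genes were higher and 430 lower and translation factors were at an adjusted p of 0.0893, and at 0.292 without the pool A array X alone.

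Against pool B, pool C had 2603 genes higher and 1923 lower. CD9, a membrane tetraspanin, was at least 5.33-fold higher and MARCKS, an actin-binding substrate of protein kinase C, 6.24-fold higher. Proteasome genes were higher for 28 of 30 and for 29 adjusted over the list alone (1.55 ± 0.09, camera adjusted p = 7.47e-13, and adjusted p = 0.0129 with an estimated correlation), with PSMA4 4.87-fold higher. ZFAS1 was 10.3-fold (adjusted p = 1.22e-06) and SNHG15, also a host of small nucleolar RNAs, 6.91-fold lower, within a noncoding list lower for 12 of 23 over all genes and 12 adjusted over the list alone (-1.47 ± 0.25, adjusted p = 1.68e-07, and adjusted p = 0.0129 with an estimated correlation). The pro-death BCL2 family genes BAD, BCL2L11 and BAX were 5.24-fold, 4.08-fold and 3.99-fold lower in pool C, and the list had 6 lower and 1 higher of 15, or 9 and 1 adjusted over the list alone (-0.87 ± 0.26, adjusted p = 0.0202, and adjusted p = 0.366 with an estimated correlation). Plasma cell identity genes were higher for 11 of 27, also adjusted over the list alone (0.45 ± 0.12, adjusted p = 0.0267, and adjusted p = 0.366 with an estimated correlation), with the surface proteins CD38 at 3.20-fold and SDC1 at 3.09-fold. Unfolded protein response genes were higher for 16 and lower for 2 of 25, also adjusted over the list alone (0.75 ± 0.17, adjusted p = 0.00353, and adjusted p = 0.366 with an estimated correlation). Heat shock genes were higher for 11 and lower for 1 of 20, with 12 and 1 adjusted over the list alone (0.72 ± 0.17, adjusted p = 0.0136, and adjusted p = 0.409 with an estimated correlation).

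Replication histones, most of whose mRNAs lack a poly(A) tail, were lower in pool C than in pool B for 5 of 13, also adjusted over the list alone (-0.94 ± 0.21, adjusted p = 0.00722, and adjusted p = 0.366 with an estimated correlation), H2BC12 by 4.49-fold. Ribosomal protein genes were lower for 18 and higher for 3 of 68, with 12 and 3 adjusted over the list alone (-0.36 ± 0.07, adjusted p = 0.0136, and adjusted p = 0.471 with an estimated correlation). EIF4EBP1 was 3.52-fold and ATF4 3.26-fold lower, and MYC 2.48-fold higher. Median scaling gave 4809 higher and 936 lower (median gene 0.64 in place of 0.13), with ribosomal genes at -0.95 (adjusted p = 7.76e-12) and plasma cell genes at an adjusted p of 0.204. When the untreated X arrays were left out, 1520 genes were higher and 1170 lower, with ribosomal genes at an adjusted p of 0.188 and BCL2 family genes at 0.0541. Leaving out the pool C array X alone gave 0.0828 for ribosomal and 0.0608 for plasma cell genes.

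Against total RNA, pool A had 1899 genes higher and 3042 lower at 0 h. Noncoding RNAs were higher as a list. RNA28SN5, the large ribosomal RNA, was 18.2-fold (adjusted p = 0.000859), SNORD14C 14.1-fold (adjusted p = 1.28e-06) and RN7SK 8.03-fold higher, and of 23 noncoding RNAs 17 were higher and 1 lower, also adjusted over the list alone (1.63 ± 0.22, camera adjusted p = 1.31e-08, and adjusted p = 0.00963 with an estimated correlation). The oligosaccharyltransferase subunit STT3A was 12.3-fold lower (adjusted p = 2.27e-06), the dynein heavy chain DYNC1H1 9.38-fold and the proliferation marker MKI67 at least 5.86-fold lower. Unfolded protein response genes were lower for 17 and higher for 1 of 25, with 20 and 2 adjusted over the list alone (-0.91 ± 0.20, adjusted p = 0.00031, and adjusted p = 0.247 with an estimated correlation), among them the chaperones HYOU1 at 5.84-fold and HSP90B1 at 5.82-fold lower. Proteasome genes were lower for 20 of 30 and for 22 adjusted over the list alone (-0.84 ± 0.12, adjusted p = 3.26e-05, and adjusted p = 0.174 with an estimated correlation). Cell cycle genes were lower for 24 and higher for 3 of 35, with 25 and 5 adjusted over the list alone (-0.71 ± 0.19, adjusted p = 0.00136, and adjusted p = 0.254 with an estimated correlation), with the spindle factor TPX2 5.44-fold lower and the transcription factor E2F1 5.11-fold higher. Aminoacyl-tRNA synthetases were lower for 11 of 18 and for 12 adjusted over the list alone (-0.80 ± 0.14, adjusted p = 0.00168, and adjusted p = 0.267 with an estimated correlation), IARS1 by 4.28-fold.

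Heat shock genes were lower in pool A than in total RNA for 15 and higher for 2 of 20, with 16 and 2 adjusted over the list alone (-0.88 ± 0.25, adjusted p = 0.00326, and adjusted p = 0.254 with an estimated correlation). Histones were higher for 5 of 13, also adjusted over the list alone (0.90 ± 0.18, adjusted p = 0.00469, and adjusted p = 0.254 with an estimated correlation). Plasma cell genes were lower for 12 and higher for 1 of 27, with 13 and 1 adjusted over the list alone (-0.45 ± 0.12, adjusted p = 0.016, and adjusted p = 0.247 with an estimated correlation). MYC targets and nucleolar genes were lower for 16 and higher for 2 of 27, also adjusted over the list alone (-0.57 ± 0.19, adjusted p = 0.0164, and adjusted p = 0.353 with an estimated correlation). Immediate early genes were higher for 7 and lower for 1 of 18, also adjusted over the list alone (0.70 ± 0.21, adjusted p = 0.0164, and adjusted p = 0.174 with an estimated correlation), among them IER3 at 5.72-fold. Ribosomal protein genes were higher for 13 and lower for 2 of 68, with 13 and 1 adjusted over the list alone (0.34 ± 0.07, adjusted p = 0.0298, and adjusted p = 0.36 with an estimated correlation). Glucocorticoid receptor targets, in which the untreated N and X arrays differed, were higher for 11 and lower for 5 of 34, with 11 and 4 adjusted over the list alone (0.48 ± 0.17, adjusted p = 0.0385, and adjusted p = 0.36 with an estimated correlation). Median scaling gave 546 higher and 5791 lower (median gene -0.87 in place of -0.19), with ribosomal genes at 1.04 (adjusted p = 1.5e-13), plasma cell genes at an adjusted p of 0.0721 and immediate early genes at 0.0532. The deposited value table gave 0.42 for immediate early genes (adjusted p = 0.0679) and 0.23 for glucocorticoid receptor targets (adjusted p = 0.101). The fit without the untreated X arrays had 1250 genes higher and 1889 lower, with ribosomal genes at an adjusted p of 0.0697. Glucocorticoid receptor targets were at 0.158 without the untreated pool A array X and 0.154 without the untreated total RNA array N, and at a shift of 0.72 (adjusted p = 0.00702) without the untreated pool A array N. Ribosomal genes were at 0.0839 without the untreated pool A array X.

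Pool B had 1852 genes higher and 2505 lower than total RNA. DYNC1H1 was 9.19-fold lower (adjusted p = 1.6e-05), STT3A 7.55-fold and the ubiquitin-activating enzyme UBA1 7.35-fold lower. Replication histones were higher for 9 of 13 and for 10 adjusted over the list alone (1.12 ± 0.17, camera adjusted p = 0.000404, and adjusted p = 0.217 with an estimated correlation), H2AC20 by 3.63-fold. BCL2 family genes were higher for 8 and lower for 2 of 15, also adjusted over the list alone (0.85 ± 0.26, adjusted p = 0.0102, and adjusted p = 0.246 with an estimated correlation), BCL2L11 by 4.15-fold and BAD by 4.11-fold, and EIF4EBP1 was 4.09-fold higher. Oxidative phosphorylation genes were higher for 18 and lower for 8 of 58, with 18 and 9 adjusted over the list alone (0.37 ± 0.10, adjusted p = 0.0102, and adjusted p = 0.561 with an estimated correlation). Proteasome genes were lower for 24 of 30 and for 25 adjusted over the list alone (-0.89 ± 0.10, adjusted p = 7.5e-07, and adjusted p = 0.161 with an estimated correlation). Aminoacyl-tRNA synthetases were lower for 15 of 18, also adjusted over the list alone (-1.05 ± 0.11, adjusted p = 9.99e-06, and adjusted p = 0.217 with an estimated correlation), EPRS1 by 3.19-fold. Cell cycle genes were lower for 25 and higher for 3 of 35, also adjusted over the list alone (-0.81 ± 0.15, adjusted p = 2.83e-05, and adjusted p = 0.217 with an estimated correlation), the mitotic kinase CDK1 by 4.07-fold.

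Heat shock genes in pool B were lower than in total RNA for 12 of 20, also adjusted over the list alone (-0.99 ± 0.21, adjusted p = 0.000407, and adjusted p = 0.237 with an estimated correlation). Unfolded protein response genes were lower for 16 and higher for 2 of 25, also adjusted over the list alone (-0.81 ± 0.21, adjusted p = 0.00117, and adjusted p = 0.246 with an estimated correlation). MYC targets and nucleolar genes were lower for 16 and higher for 3 of 27, with 17 and 3 adjusted over the list alone (-0.69 ± 0.20, adjusted p = 0.000682, and adjusted p = 0.246 with an estimated correlation), and MYC itself was 2.33-fold lower. Sterol synthesis genes were lower for 11 and higher for 1 of 20, with 13 and 1 adjusted over the list alone (-0.57 ± 0.18, adjusted p = 0.0217, and adjusted p = 0.493 with an estimated correlation). Median scaling gave 1121 higher and 3809 lower around a median gene of -0.40 in place of -0.11, with oxidative phosphorylation genes at 0.75 (adjusted p = 1.19e-07). In the fit without the untreated X arrays 900 genes were higher and 1275 lower, with oxidative phosphorylation genes at an adjusted p of 0.119 and sterol genes at 0.106. The former were at 0.0571 without the pool B array X alone and the latter at 0.0629 without the total RNA array X alone.

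**Figure D3:**
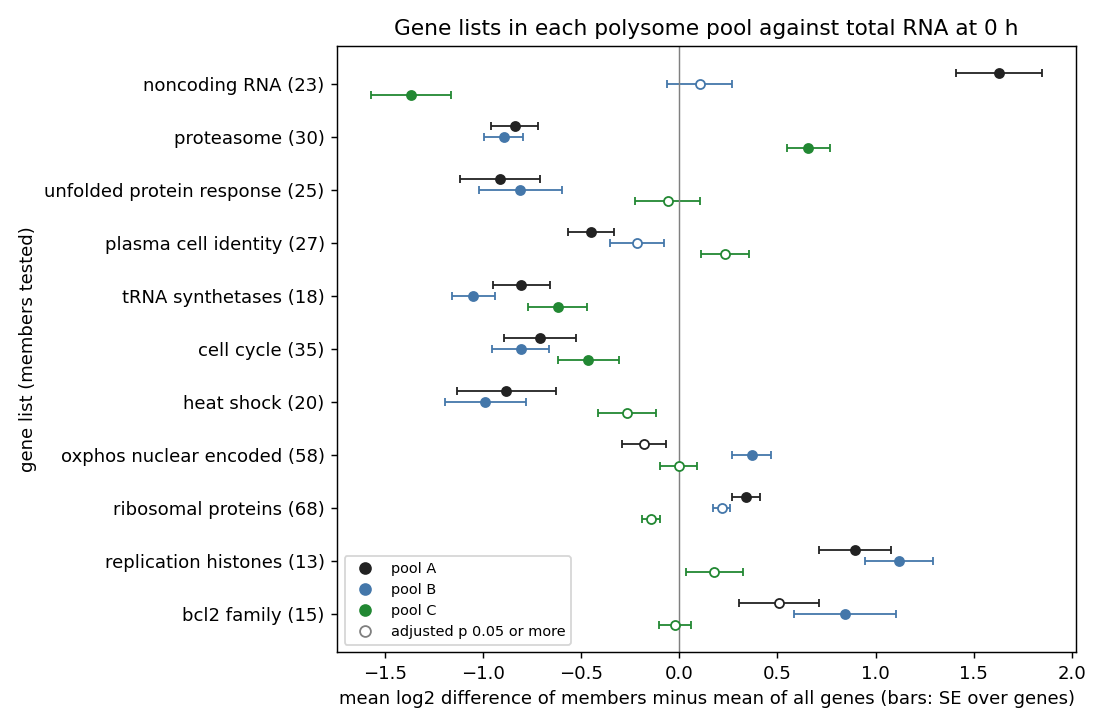
Mean log2 difference of 11 gene lists between pools A, B and C and total RNA at 0 h minus the mean of all genes (horizontal axis); bars are standard errors over genes and open symbols have an adjusted p of 0.05 or more. Proteasome genes lie at -0.84 in pool A, -0.89 in pool B and 0.66 in pool C.

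Pool C had 1428 genes higher and 1546 lower than total RNA. RSPRY1, a RING finger protein, was 12.3-fold higher (adjusted p = 0.00139). Noncoding RNAs were lower, SNORA61 by 33.6-fold (adjusted p = 2.31e-06), SNHG5 by 9.10-fold and RN7SK by 5.99-fold, in a list lower for 15 of 23, also adjusted over the list alone (-1.37 ± 0.20, camera adjusted p = 1.22e-09, and adjusted p = 0.00657 with an estimated correlation). The scaffold protein IQGAP1 was at least 11-fold lower. Proteasome genes were higher for 14 and lower for 1 of 30, with 16 and 1 adjusted over the list alone (0.66 ± 0.11, adjusted p = 3.39e-06, and adjusted p = 0.118 with an estimated correlation). The core subunits PSMA4 and PSMA2 were 2.84-fold and 2.55-fold higher and the cap subunit PSMD1 3.38-fold lower. Aminoacyl-tRNA synthetases were lower for 9 of 18, also adjusted over the list alone (-0.62 ± 0.15, adjusted p = 0.00191, and adjusted p = 0.74 with an estimated correlation), EPRS1 by 2.96-fold. Cell cycle genes were lower for 13 and higher for 1 of 35, with 15 and 5 adjusted over the list alone (-0.46 ± 0.16, adjusted p = 0.0364, and adjusted p = 0.765 with an estimated correlation), with the replication helicase subunit MCM2 4.54-fold and MKI67 4.42-fold lower. ATF4 was 3.39-fold lower. Median scaling gave 2761 higher and 1166 lower (median gene 0.28 in place of 0.06), with tRNA synthetases at an adjusted p of 0.153 and cell cycle genes at 0.355, and cell cycle genes were at -0.26 in the deposited value table (adjusted p = 0.157). The total was 1666 without the untreated pool C array N (cell cycle adjusted p = 0.175), 1898 without X, 1578 without the untreated total RNA array N and 1523 without X (cell cycle adjusted p = 0.0965). With all 4 untreated X arrays left out 334 genes were higher and 729 lower.

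Lists of mTOR and translation control (26 tested members), the integrated stress response (21), interferon-stimulated genes (15) and cytokine signalling (21) were not shifted past the threshold in any of the 14 comparisons. Neither were markers of T cells (3 tested members), myeloid cells (3), stromal cells (4) and erythroid cells (3), fixed as a check for other cell types. These comparisons cannot show other cells present alike in both groups, or a difference between N and X arrays. The mean X minus N difference of the erythroid list was negative in every group, from -0.413 to -1.34. That of the stromal list was positive in every group, from 0.159 to 0.812. The T cell and myeloid lists had both signs, and the cause was not tested.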

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

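The tests of 1 share of treated material and of a batch difference were chosen after the difference between the untreated arrays had been seen, and the other tests before their results.

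Glucocorticoid receptor targets stood higher on the untreated X than on the untreated N arrays in every kind of RNA, by a mean of 0.45 log2 units over the list, and DDIT4, TSC22D3, CXCR4 and KLF9 by at least 1.269 in each. The median over the members was 0.0716 in total RNA, 0.414 in pool A, 0.372 in pool B and 0.135 in pool C. In total RNA and pool C the mean was thus carried by a part of the members. A batch difference between N and X arrays of equal size at both times is argued against as the whole cause by the mean difference at 4 h, 0.0776. That difference ranged from 0.0139 in total RNA to 0.145 in pool B, there at the 99.78th percentile of matched lists. A batch difference that the treatment evens out cannot be judged at 4 h, where both arrays were treated, and stays open. A part of a batch difference at both times also stays open. In the value table the list was at 0.359 in pool A and 0.469 in pool B at 4 h. Relative to all genes it was at 0.11 and 0.164, against 0.394 and 0.459 at 0 h. Exposure of the untreated X sample to a glucocorticoid may account for the difference. The 25 members not inspected before lay between the 99.96th and the 100th percentile of 10000 matched random lists in 4 of 4 kinds of RNA. These percentiles compare genes within 1 pair of arrays, treat members as independent and measure no spread between samples. Differences between the 2 untreated arrays also correlated across genes between kinds of RNA (0.25 to 0.403), so the 4 kinds are not independent. A mix with treated material would give such percentiles as well. For such a mix in 1 fixed share, the first test was undecided (0.477 of the variance in the share of the rise of 42 genes lay between genes, within the bounds set for it), and a second, added afterwards, gave departures from a common share with an SD 1.28 times that between the 4 h arrays, within the bound of 1.5 set for a common share, while 10 genes lay under 0.15 of their rise in all 4 kinds of RNA (CEP70 at a mean of 0.00762, HMGB3 at 0.0643) and 7 over 0.3 (DDIT4 at 0.614, TSC22D3 at 0.458). These genes, picked for extreme values, do not exclude 1 share, since the 2 samples also differed otherwise (HBD and HLA-DRA, picked after their values were seen, had a mean X minus N difference of -1.55 and -1.50 at 0 h and of -1.38 and -1.69 at 4 h), so that exposure and carry-over of treated RNA stay open, and no biological explanation was tested, since the design names no difference between the 2 samples.

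Pool A had 89 calls for dexamethasone and total RNA 11, although the difference between the responses called 0 genes in limma (410 at an unadjusted p under 0.05). A larger spread in pool A than the shared error allows for is a candidate explanation: fitted on its own arrays, pool A had 0 calls (789 at an unadjusted p under 0.05) and total RNA 20, and array weights of 0.711 against 1.73 gave 13 and 91. Genes near background are another, since among the 6521 genes detected on all 16 arrays the counts were 41 and 28. A larger response of pool A, the biological explanation, cannot be told apart from these: 42 of the 89 genes differed from total RNA when adjusted over these genes alone, but the 89 were chosen for their change in pool A, which makes that test void. The spread and the genes near background stay open together.

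The test of the difference between the responses of pool B and total RNA passed for heat shock genes (0.25 higher in pool B relative to all genes, 15 of 20 members, camera adjusted p = 0.0176, and 0.94 with an estimated correlation) and for proteasome genes (0.156 higher, 23 of 30 members, adjusted p = 0.0385, and 0.94 with an estimated correlation). Both had 0 members at an unadjusted p under 0.05 (limma), and the adjusted p was 0.1 and 0.408 without the untreated X arrays and 0.328 and 0.125 with no filter on dim probes. Without the untreated pool B array X, the untreated total RNA array N, the treated pool B array X or the treated total RNA array X it was 0.398, 0.476 (shift 0.12), 0.175 and 0.406 for heat shock genes, and 0.294, 0.0949, 0.556 and 0.286 for proteasome genes, with 0.138 for the latter without the untreated total RNA array X. Probes without a gene name were outside the gene comparisons, and of 3980 such probes 2 passed for dexamethasone in total RNA, 11 in pool A, 6 in pool B and 6 in pool C.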

How the results depend on the processing

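The block for the column prefix, the array weights, the fits of the value table with a block and the fit without the untreated X arrays were chosen after the data were seen. Counts of genes follow for dexamethasone in total RNA and pools A, B and C (main values 11, 89, 3 and 7) where they moved by over 1.5 times, and the cause was not tested unless stated. No background correction gave 37 in total RNA, 6 in pool B and 22 in pool C, sharing 8, 3 and 6 genes with the main counts. Median scaling gave 5, 43, 0 (656 at an unadjusted p under 0.05) and 14, and 3806 for pool B against pool A. Quantile normalization within each kind of RNA gave 23 in pool A and 16 in pool C. The deposited value table gave 7 in total RNA, 53 in pool A, 0 in pool B (301 at an unadjusted p under 0.05) and 1370 for pool B against pool A. With detection on all 16 arrays, which tests fewer genes, there were 28, 41 and 6 in total RNA, pool A and pool B, and the mean of a gene's probes gave 19 in total RNA. Fits of only the groups compared, which have fewer arrays, gave 20 in total RNA, 0 in each pool (789, 508 and 507 at an unadjusted p under 0.05) and 727 for pool B against pool A. Trend and robust settings gave 37, 10 and 20 in total RNA, pool B and pool C. Array weights gave 91 in total RNA, 13 in pool A and 1 in pool B. The fit without the untreated X arrays, with fewer arrays, gave 26 in total RNA, 14 in pool B and 20 in pool C, and among the untreated comparisons 865 for pool B against pool A, 2690 for pool C against pool B, and 3139, 2175 and 1063 for pools A, B and C against total RNA. No filter on dim probes moved none of the 14 counts by over 1.5 times. In the value table the higher and lower genes were 4301 and 1282 for pool C against pool A, 3874 and 792 for pool C against pool B, 52 and 1 for dexamethasone in pool A, 1043 and 3222, 897 and 3091, and 2088 and 1008 for pools A, B and C against total RNA.

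Replicate numbers stand on the value table only, and the arrays of different groups share a number with no stated culture. Deviations of equal numbers correlated across genes above 0.1 in 27 of 28 pairs of groups (-0.0557 to 0.435, median 0.308; by prefix -0.0762 to 0.403, median 0.246). The value table with a replicate block gave 60, 580, 20 and 44 genes in total RNA and pools A, B and C. With a culture block (time and number, correlation 0.232) it gave 0 in pool B (311 at an unadjusted p under 0.05) and 13 in pool C. The prefix block gave 50, 213, 13 and 32, and 1 for the response of pool C minus that of pool A; FKBP5 (adjusted p = 0.0372), IRF4 (0.0234), TXNIP (0.0482) and CCL3 (0.0372) passed in total RNA and CCL3 in pool C (0.0435), and the cell cycle list of pool C against total RNA was at 0.0587. No slide block was run, since the files name no slide.

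Leaving out 1 array at a time assumes that the lone array of a group varies like the others. Counts were 0 to 0 in total RNA (253 to 419 at an unadjusted p under 0.05), 13 (without treated N) to 93 in pool A, 38 there without treated X, 0 to 0 in pool B (462 to 1314) and 0 (without treated X, 422) to 48 (without treated N) in pool C, with 1 without untreated N and 3 without untreated X there. Differences of responses gave 0 to 16 for pool A minus total RNA, 16 without the untreated pool A array N (684), 0 to 0 for pool B (111 to 375), 0 to 0 for pool C (92 to 446) and 0 to 8 for pool C minus pool A, 8 again without the untreated pool A array N. Untreated comparisons gave 4372 to 5173 for pool C against A, 1863 to 2177 for B against A, 3099 to 3908 for C against B, and 3617 to 4377, 2957 to 3873 and 1523 to 1898 for pools A, B and C against total RNA. For pool C the last count was 1666 without the untreated pool C array N, 1898 without X, and 1578 and 1523 without the untreated total RNA arrays N and X. Each such fit has fewer arrays.

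Of values for named genes under the alternatives, 3098 kept their side of the threshold, 303 lost a call and 48 gained one. Direction was compared only for genes called in the main fit. For called gene lists 925 kept direction and call and 157 lost the call. Of the 58 list calls, 7 held with an estimated correlation, and for 40 fry also passed, which tests for change of the list and not against other genes. The called lists that kept their call but moved by over 1.5 times follow, apart from median scaling and left-out arrays. The value table gave ribosomal protein genes at -0.89 (pool C against A), -0.58 (C against B) and 0.69 (A against total RNA), histones at 0.59 and 0.62 (A and B against total RNA), BCL2 family genes at -0.55 (C against B) and 0.55 (B against total RNA), noncoding RNAs at -0.98 (B against A), and for dexamethasone sterol genes at -0.13 in pool A and nucleolar genes at -0.16 in pool B. With a replicate block the table had immediate early genes at 0.42 (A against total RNA, adjusted p = 0.0447). With no background correction nucleolar genes were at -0.16 in pools A and B, noncoding RNAs at -0.99 (B against A), histones at -0.45 (C against B), 0.46 and 0.52 (A and B against total RNA) and glucocorticoid receptor targets at 0.30 (A against total RNA). Histones were at -0.46, 0.38 and 0.52 in these comparisons with no filter, and noncoding RNAs at -0.78 (B against A) and -2.23 (C against B) with detection on all arrays. No direction of a called list, or of a called gene among those named, turned. The directions of the other called genes, and of named genes not called in the main fit, were not checked. Low signal over background limits genes such as FZD4, TLE1 and CEMIP, for which only bounds or no folds could be given.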

Other observations

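The tests of this part were set before their results were seen, on lists of genes with very long or very short coding regions that were written from general knowledge after the pool comparisons had been seen.

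Nuclear-encoded genes of oxidative phosphorylation split between pools C and A at 0 h, with 32 higher and 14 lower of 58 (32 and 15 adjusted over the list alone), and the list was not shifted past the threshold (camera adjusted p = 0.259). The complex I subunit NDUFC1 was 10.5-fold lower and the complex III subunit UQCR10 7.18-fold lower in pool C. MT2A, a metallothionein, was 8.37-fold lower. Against pool B, pool C had 16 higher and 24 lower members of the same list (the same counts adjusted over the list alone, adjusted p = 0.0932).

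Genes with very long coding regions were lower in every pool than in total RNA at 0 h, by -1.13 ± 0.126 in pool A (33 of 47 lower), -0.989 ± 0.117 in pool B (31 lower) and -1.16 ± 0.116 in pool C (29 lower), relative to all genes. Genes with very short coding regions were at 0.719 ± 0.126 in pool A (24 of 43 higher), 1.07 ± 0.0897 in pool B (32 higher) and -0.552 ± 0.118 in pool C (16 lower). Normalization is argued against for the long list, since it stayed at -1.24 in pool C under median scaling. The short list was then at 1.01, 1.4 and -0.365 in pools A, B and C. Chance levels of the shared untreated total RNA arrays are argued against by 4 h, on other arrays, where the highest of the 3 pools was -1.19 for the long list. An order of pools A, B and C by ribosome load would raise long coding regions from A to C. No such rise was seen, with a difference of -0.03 ± 0.115 between pools C and A. Other values go with an order: noncoding RNAs were at 1.63, 0.10 and -1.37 in these pools against total RNA, and the short list was lowest in pool C. A loss of long RNA that differs between pools could hide a rise, so the order stays open. Coding length, or a property that goes with it, such as RNA length and its loss during fractionation or labelling, may take part, since the short list exceeded the long one in each pool, by 0.608 ± 0.165 at the least (pool C), and coding lengths themselves were not measured here.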
